A study of Saccharomyces cerevisiae with 92 samples.

How the data were processed

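Peak lists from 89 of 92 samples were used. The 3 samples without a list here were both Abf1 ChIP-exo samples and INO80 replicate 2, and they were not analysed here. Each list gives the chromosome, strand, interval and value of each peak. The deposited value is a score, which per the file headers is only called a value, and which was taken as the authors' height of a peak of read ends on a single strand. It follows the depth of a library, so it was used only to filter or weight peaks within a list and never compared between lists. Peaks had been called by the authors per sample and per strand, as the deposited lists show, and every interval spans 147 bp. Base calling with CASAVA 1.7 and bcl2fastq 2.16 and alignment with BWA 0.6.2 and 0.7.9a are named per the submitters' processing notes, without saying which samples each version served. The peak caller's version and the genome build are not given in the sources used here, and neither is the number of reads per library. Depth is therefore described by the number of peaks, 68440 to 100204 in the 88 complete lists.

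Groups were taken from the sample labels. The sample codes in the labels begin with PSU (73 lists) or LMU (16 lists), and this prefix was treated as a batch, as was the assay. The largest share of identical peak positions between lists was 3.76%, so none was treated as a repeat of another. A list without peaks on 3 or more chromosomes counted as incomplete, which removed 1 list with 66087 peaks.

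Peaks with at least 0.5 times the median score of their own list were kept. For each library the strand offset was the most common distance from plus to minus strand peaks between 100 and 200 bp, and it ranged from 109 to 168 bp. Plus and minus peaks that were each other's nearest partners within 40 bp of that offset were paired, and the middle of a pair was taken as a nucleosome midpoint. Pairing used 44.1 to 81.8% of the peaks. The plan made before the data were examined spoke of peak midpoints, and pairing was added when the lists turned out to be specific to a strand. Spacing was the median of the distances up to 300 bp between consecutive midpoints, and gaps over 250 bp were counted per Mb. Distances up to 700 bp between midpoints were smoothed (Gaussian, SD 8 bp) and divided by their expectation from even coverage. The repeat length was the first maximum between 130 and 240 bp, the second maximum was sought between 300 and 480 bp, and array contrast was the first maximum minus the lowest value in the 120 bp after it. Its error in a single library was a jackknife over the 16 chromosomes. Shared positions lay within 20 bp.

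Group means of spacing, gaps, repeat length and the region index were compared by exact two-sided permutation of the library labels, with Benjamini-Hochberg adjustment within each family, and by permutation with 100000 resamples for sharing and for the variance between treatments. Nucleosome density was computed every 50 bp from retained peaks shifted by the offset toward the midpoint (Gaussian, SD 30 bp) and divided by its mean over the genome. At the 211799 points with a mean of at least 0.1, log2(density + 0.5) was fitted with limma 3.58.1 (trend) on all groups with 2 or more libraries, with the assay as a covariate. Points with an adjusted p under 0.05 in one direction were merged within 100 bp. A log2 difference in density plus 0.5 understates changes to or from low density. Regions named in the text come from the 4 largest changes in each direction whose libraries did not overlap between groups. This rule was made after the data were seen, since the rule fixed before named genes.

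Spacing, gaps, sharing and the INO80 values had been planned before the data were examined. Repeat length, array contrast, density regions, the index of regions in other mixtures and all their alternatives were added after the lists were seen. The planned results at start codons, promoters, poly(dA) runs, Abf1 and Reb1 motifs, gene lists and named genes need a genome of the build of the lists, and without one they were not run. Gene tables of assembly R64 were not used.

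The repeat length was tested on 8 simulated lists of evenly spaced arrays and erred by at most 1 bp. Irregular arrays were not simulated. In the libraries the first and second maxima often disagreed, as in SGD with means of 172 and 186 bp. The test therefore does not give the error in these libraries. The density model was tested on simulated data with 200 changed points. In RSC against SGD it recovered 0% of increases of 1 in log2, 5.5% at 2, 60% at 3 and 96% at 4. In SWI/SNF against SGD these shares were 0%, 0%, 45% and 84%, and in the Abf1 against Reb1 mixtures 0%, 19%, 74.5% and 96.5%. Of decreases of 3, 100% were recovered in each, but decreases were drawn only from points of high density. There the median residual SD was 0.31 to 0.33, against 0.86 to 0.87 for increases of 3. The shares therefore do not compare the power for losses and gains. False calls in SWI/SNF against SGD were 22 of 222 called points for decreases of 3, 11 of 101 for increases of 3 and 2 of 14 for decreases of 2. These shares are above the nominal rate. The model had been run on the lists once before this test was complete, and the test now comes first.

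Alternatives varied the peak filter (all peaks, or those at or above the median score), score weighting (capped at the percentile 99), the sharing distance (10 and 40 bp), the longest distance taken for spacing (250 bp), the groups used to call the regions of the index, the pseudocount (0.25 and 1), the assay, prefix and groups in the fit, single strands, the second maximum (also without libraries at a limit of its search), single libraries left out and replicate numbers as a block. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.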

Results

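Nucleosome positions were mapped on a yeast genomic DNA library that had been assembled in vitro with Drosophila embryo histones by salt gradient dialysis (SGD). The assembled material was left as it was, or received purified ATP-dependent remodellers, sequence-specific general regulatory factors, or whole-cell extract. The remodellers were RSC and SWI/SNF, the ISWI-type enzymes ISW1a, ISW1b and ISW2, Chd1, and INO80 with a variant labelled INO80Arp8Δ. The factors were Abf1 and Reb1, which bind their own DNA motifs at many yeast promoters. Extracts came from wild-type cells, from rsc3-ts cells and from isw1Δisw2Δchd1Δ cells, and the last of these is called the extract below. Micrococcal nuclease (MNase) digestion was followed by sequencing, either directly (MNase-Seq) or after precipitation with an antibody to histone H3 (MNase-ChIP-Seq). The series held 92 samples in 40 groups. Peak lists of 89 samples from 39 groups were read, 57 from MNase-Seq and 32 from MNase-ChIP-Seq. A single list, Reb1+ISW2+ISW1a+RSC+ISW1b+Chd1 replicate 1, had peaks on only 13 of the 16 chromosomes and entered no test. The other 88 lists held 68440 to 100204 peaks each, from which 14418 to 30906 nucleosomes per library were placed. Of their groups, 20 had 2 or more libraries and 19 had 1. Group means are given with the SD between libraries. The labels do not say that replicates were separate reconstitutions, so p-values measure the spread between these samples, which may be technical. Names of some lists hint that replicates differ in the amount of remodeller or in the degree of digestion, which the labels do not give, so that spread may also include such differences.

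Libraries of the same treatment placed nucleosomes at the same sites far more often than libraries of different treatments did. Within treatments, 43.7 ± 9.63% of nucleosomes (SD, 129 pairs of libraries) lay within 20 bp of a nucleosome of the other library. Between treatments the share was 28.6 ± 8.03% (2217 pairs), and it was 8.92% after one list was shifted by 1 kb. Libraries with SWI/SNF or Abf1 shared about as many positions with SGD as SGD libraries shared with each other: 53.9 ± 2.67% (n = 2) and 55.6% (n = 1) of their nucleosomes were shared with SGD libraries, against 52.6 ± 4.21% among the 4 SGD libraries. The share was 38.6 ± 3.53% with Chd1, 33.9 ± 1.58% with ISW1b, 30.4 ± 7.73% with ISW1a, 26.1 ± 2.77% with ISW2 (n = 2 each), 25.8 ± 3.23% with RSC (n = 3) and 27.4% with INO80 (n = 1). With wild-type extract it was 19.1% (n = 1). The difference of 15.1 percentage points within against between treatments had a permutation p of 1e-05 (one-sided), the smallest that 100000 resamples can give. It was 13.8 points among pairs of the same assay and 16.2 points among pairs with the same sample code prefix, PSU or LMU. Libraries of a treatment often had neighbouring code numbers, as those of RSC did. Such series within a prefix were not tested and cannot be told apart from the treatment there.

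The next comparison asked which remodeller, acting alone, sets a distance between neighbouring nucleosomes. The repeat length, the most common distance between nucleosomes at the first maximum of the pair correlation, was 172 ± 1.41 bp in SGD (n = 4). It was 178 ± 1.0 bp with RSC (n = 3), and with n = 2 each 184.5 ± 2.12 bp with ISW2, 182.5 ± 6.36 bp with ISW1a, 180.0 ± 1.41 bp with ISW1b, 180.0 ± 1.41 bp with SWI/SNF and 176 ± 5.66 bp with Chd1. Every library of RSC, ISW2, ISW1a, ISW1b and SWI/SNF lay above every SGD library, and 1 of the 2 Chd1 libraries did. So did Abf1 alone at 178 bp and Reb1 alone at 175 bp (n = 1 each), without a remodeller. Mean strand offsets were 145 bp in SGD and longer with each of the 6 remodellers, from 148 bp with ISW1a to 163 bp with SWI/SNF. Abf1 alone stood at 160 bp and Reb1 alone at 136 bp. Whether fragment length contributed to the longer repeats was not tested. Grouping by treatment accounted for 74.8% of the variance of repeat length over 69 libraries of 20 treatments (permutation p = 1e-05, the smallest possible). Labels were permuted without regard to the assay, which was unevenly spread over treatments. Random labels in 20 groups would also take up part of the variance. The single comparisons with SGD did not pass correction. The exact two-sided permutation p was 0.0286 for RSC, the smallest that 3 against 4 allows, and 0.0667 for ISW2, ISW1a, ISW1b and SWI/SNF, the smallest that 2 against 4 allows, with adjusted p = 0.08 over 6 comparisons. For Chd1 the exact p was 0.267. The ISW1a difference of 10.5 bp was 6.0 and 15 bp without ISW1a replicates 1 and 2. Within MNase-ChIP-Seq the differences from SGD were 6.33 bp for RSC, 8.33 bp for SWI/SNF, 12.8 bp for ISW2 and 0.333 bp for Chd1. Within MNase-Seq, which held 1 SGD library, they were 9.5 bp for ISW1a, 7.0 bp for ISW1b and 7.0 bp for Chd1. Spacing taken from the second maximum of the pair correlation, an alternative chosen after the data were seen, kept the sign for ISW2 alone, at 3.75 bp; the others turned to -5.33 bp for RSC, -0.50 bp for SWI/SNF, -15.5 bp for Chd1, -16.5 bp for ISW1a and -15.0 bp for ISW1b. For Chd1 the difference of 4.0 bp also became -0.25 bp when peaks were weighted by score, and 0 and 8.0 bp without Chd1 replicates 1 and 2.

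The median distance between consecutive nucleosomes, taken over distances up to 300 bp, was 202 ± 1.38 bp in SGD (n = 4) and 213.8 ± 2.41 bp with RSC (n = 3). It was 209.8 ± 7.42 bp with ISW1a, 207.8 ± 1.77 bp with ISW2, 205.0 ± 0.707 bp with ISW1b, 203 ± 1.06 bp with SWI/SNF and 199 ± 14.5 bp with Chd1 (n = 2 each). RSC differed by 11.6 bp (exact permutation p = 0.0286, adjusted p = 0.133), with all 3 RSC libraries above all 4 SGD libraries and 11.4 bp within MNase-ChIP-Seq. With distances up to 250 bp it was 5.88 bp, below ISW2 at 6.88 bp and ISW1a at 6.12 bp, and with single strands 6.5 bp. The ISW1a difference of 7.62 bp was 2.38 and 12.9 bp without ISW1a replicates 1 and 2. No other difference had an exact p below 0.0667, and no comparison in this family of 6 passed correction. The 2 Chd1 libraries lay on opposite sides of SGD: the difference of -3.38 bp was 7.5 bp in MNase-Seq, -13.8 bp in MNase-ChIP-Seq, -13.6 bp without Chd1 replicate 1 and 6.88 bp without Chd1 replicate 2. Gaps over 250 bp numbered 1182 ± 114 per Mb in SGD (n = 4) and 1223 ± 150 per Mb with RSC (n = 3), and none of the 6 differences in gaps had an exact adjusted p below 0.6.

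**Figure D1:**
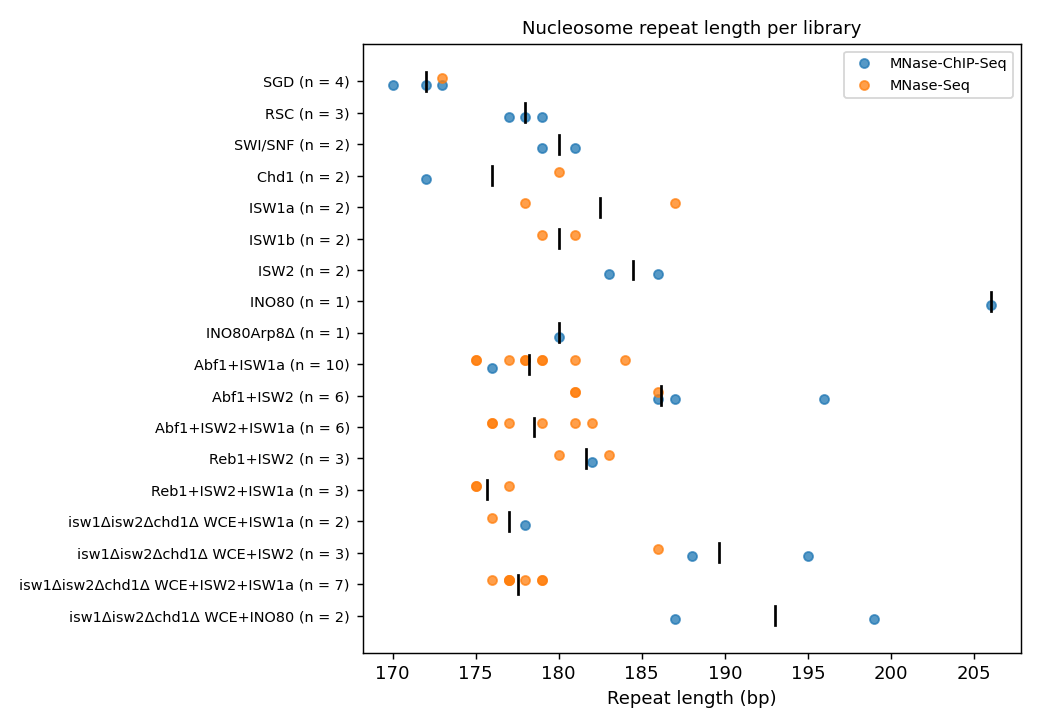
Repeat length in bp (horizontal axis) of each library, with treatments on the vertical axis, points coloured by assay and the vertical bar at the group mean. The 4 SGD libraries lie between 170 and 173 bp, INO80 stands at 206 bp, and the extract libraries with ISW2 (n = 3) lie above those with ISW2 and ISW1a (n = 7).

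Of the 6 remodellers compared with SGD, RSC and ISW2 changed nucleosome density in the most regions when all groups were fitted together. Nucleosome density, relative to the mean over the genome, was compared at 211799 positions with limma. RSC changed it in 10433 regions against SGD, higher in 5426 and lower in 5007, and ISW2 changed it in 2891, higher in 1556 and lower in 1335. Chd1 gave 326 higher and 382 lower regions, ISW1a 245 and 212, ISW1b 157 and 85, and SWI/SNF 73 and 60. With RSC, lost and gained positions often adjoined. A higher region lay within 200 bp of 58.2% of the lower regions, against 23.4% when the lower regions were shifted by 1 kb. With ISW2 these shares were 34.8% and 7.34%, and with ISW1a 25% and 1.89%. They were 15% and 0% with SWI/SNF, 14.4% and 1.57% with Chd1, and 10.6% and 0% with ISW1b.

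At chromosome 14, 639255 to 639305, nucleosome density was 4.01 ± 0.145 with RSC (n = 3) and 0.00487 ± 0.00354 in SGD (n = 4), a log2 difference of 3.35 in density plus 0.5 (limma adjusted p = 0.00015). At chromosome 14, 234355 to 234405, it fell from 4.36 ± 0.366 in SGD to 0.00737 ± 0.00809 with RSC (log2 difference -3.44, adjusted p = 0.00157). With ISW2, density at chromosome 15, 109605, was 4.89 ± 0.674 (n = 2) against 0.000573 ± 0.000384 in SGD (log2 difference 3.48, adjusted p = 0.0153). At chromosome 7, 473905 to 473955, it was 0.00782 ± 0.00522 with ISW2 against 4.35 ± 0.343 (log2 difference -3.40, adjusted p = 0.0125). With ISW1a, density was higher at chromosome 14, 205355 (4.33 ± 0.675 against 0.0157 ± 0.00236 in SGD) and lower at chromosome 12, 503855 (0.00344 ± 0.00112 against 4.35 ± 0.277). With Chd1 it was higher at chromosome 14, 455605 (5.13 ± 0.718 against 0.0607 ± 0.0289) and lower at chromosome 7, 740405 (0.0114 ± 0.00604 against 4.41 ± 0.311). ISW1b libraries held a nucleosome at chromosome 9, 345405 (3.20 ± 0.0251 against 0.0163 ± 0.0326) and lacked the nucleosome at chromosome 6, 189305 (0.0175 ± 0.0113 against 3.60 ± 0.659). With SWI/SNF, density on chromosome 1 rose at 149405 (4.01 ± 0.19 against 0.00064 ± 0.00128) and fell at 149555, where both SWI/SNF libraries were at 0 and SGD stood at 4.44 ± 0.232. These last 8 positions had limma adjusted p-values from 0.00103 to 0.0499. Coordinates are those of the peak lists, whose genome build is not given in the sources used here, so no gene is named.

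The counts depended on single libraries and on the model. For RSC they were 4940 and 5265 without RSC replicates 2 and 3, and 6185 without SGD replicate 3. For ISW2 they were 243 and 990 without ISW2 replicates 1 and 2, and 1113 and 1095 without SGD replicates 1 and 3. For Chd1 they were 222 and 288 without its replicates 1 and 2, and 330 and 340 without SGD replicates 1 and 3. For ISW1a they were 8 and 193 without its replicates 1 and 2, and 275 and 264 without the same SGD libraries. For ISW1b the count was 371 without its replicate 2 and 160 without SGD replicate 1, and for SWI/SNF 82 without its replicate 1 and 84 without SGD replicate 1. When only the 2 groups compared entered the fit, limma called 0 regions for ISW2, Chd1 and SWI/SNF, with 31648, 20165 and 12210 positions at an unadjusted p under 0.05, but 4843 for ISW1a, 2984 for ISW1b and 9677 for RSC. With the assay in that fit, ISW1a and ISW1b, all MNase-Seq, were in effect set against the 1 MNase-Seq library of SGD. The balance of directions turned with the model as well. In that fit 4014 of the 4843 regions of ISW1a and 2496 of the 2984 of ISW1b were lower, and within MNase-Seq ISW1a gave 217 higher and 338 lower and ISW1b 121 and 234. On simulated changes of 2 in log2 the RSC model recovered 5.5% of increases and 19% of decreases, so these counts are no measure of how many positions stayed unchanged. The decreases were simulated only at positions of higher density, with a median residual SD of 0.702 against 0.884 for the increases.

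The positions that RSC changed alone also differed when RSC was used with a factor. The regions called between RSC and SGD were measured in mixtures outside that contrast, as the mean log2(density + 0.5) of the higher regions minus that of the lower regions. The fit that called them held these mixtures too, for the spread and the assay term. This index was 0.62 ± 0.52 with Abf1+RSC (n = 3), -0.40 ± 0.39 with Abf1+ISW2 (n = 6) and -0.40 ± 0.41 with Abf1+ISW1a (n = 10). All 3 Abf1+RSC libraries exceeded all libraries of both other groups. The index is also low where positions stay near those of SGD, whose libraries gave -2.29 to -1.79. Abf1+ISW1a replicates 3, 9 and 10, which shared most with SGD in their group, gave -0.90, -1.22 and -0.72. When RSC was added to Reb1+ISW2+ISW1a the index went from -0.31 ± 0.26 to 0.31 ± 0.51 (n = 3 each). Reb1+RSC gave 1.85 and Reb1 alone -0.99, and Abf1 alone -1.69 (n = 1 each). The extract with added RSC gave 0.98, near the 0.93 of the extract without additions (n = 1 each). That extract lacks ISW1, ISW2 and Chd1 but is not labelled as lacking RSC, so these values do not compare RSC with its absence. Abf1+RSC differed from Abf1+ISW2 by 1.02 (exact permutation p = 0.0119, adjusted p = 0.0179) and from Abf1+ISW1a by 1.02 (exact p = 0.00699, adjusted p = 0.0179). Over the regions called with only RSC and SGD in the fit these differences were 0.89 and 0.93 (exact adjusted p = 0.0179 each). The Reb1 difference of 0.62 had an exact p of 0.1, the smallest that 3 against 3 allows, and was 0.32 without Reb1+ISW2+ISW1a+RSC replicate 1. Within MNase-Seq the difference from Abf1+ISW2 was 1.46 and within MNase-ChIP-Seq 0.32, and from Abf1+ISW1a it was 1.00 within MNase-ChIP-Seq; these values had too few libraries to pass (exact adjusted p of 0.1 to 1). Leaving out Abf1+RSC replicate 1, 2 or 3 gave 1.28, 0.76 and 1.02 against Abf1+ISW2, none with an exact adjusted p below 0.05, and 0.76 against Abf1+ISW1a without replicate 2 (exact adjusted p = 0.0682).

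The positions that ISW2 changed alone likewise differed in other mixtures. The index over the regions called between ISW2 and SGD was 0.92 ± 0.50 with Abf1+ISW2 (n = 6) and 0.01 ± 0.48 with Abf1+ISW1a (n = 10), and 5 of the 6 Abf1+ISW2 libraries exceeded all 10 of the others. In the extract it was 1.13 ± 0.08 with ISW2 (n = 3) and 0.39 ± 0.29 with ISW1a (n = 2), against 0.68 in the extract alone and 0.97 in wild-type extract (n = 1 each). The first difference, 0.92, had an exact permutation p of 0.0035 (adjusted p = 0.00699), and the one in the extract, 0.74, an exact p of 0.1, the smallest possible there. Within MNase-Seq the first difference was 0.62 (exact adjusted p = 0.1), within MNase-ChIP-Seq 1.80 (exact adjusted p = 0.25) and among PSU libraries 0.87 (exact p = 0.00799). The SGD libraries gave -2.34 to -1.73, so the index is also low where positions stay near those of SGD. Abf1+ISW1a replicates 3, 9 and 10 shared 45.0, 47.6 and 40.9% of positions with SGD and gave -0.66, -0.82 and -0.41. The other Abf1+ISW1a libraries gave -0.06 to 0.56, and ISW1a without Abf1 gave 0.78 and 0.14.

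Mixtures with Abf1 and with Reb1, each combined with ISW2 and ISW1a, placed nucleosomes at different positions. Abf1+ISW2+ISW1a (n = 6) and Reb1+ISW2+ISW1a (n = 3) differed in 448 regions, 195 higher and 253 lower with Abf1. At chromosome 4, 1480255, density was 4.31 ± 0.388 with Abf1 and 0.00241 ± 0.00148 with Reb1 (log2 difference 3.25, limma adjusted p = 6.54e-05). At chromosome 14, 339605, it was 4.27 ± 0.423 and 0.00863 ± 0.0131 (log2 difference 3.23, adjusted p = 0.000287). The reverse held at chromosome 16, 261455, with 0.0546 ± 0.0625 with Abf1 and 3.99 ± 0.271 with Reb1 (log2 difference -3.02, adjusted p = 0.00172). It also held at chromosome 4, 442605, with 0.067 ± 0.0479 and 4.06 ± 0.145 (log2 difference -3.01, adjusted p = 0.0291). Without Reb1+ISW2+ISW1a replicate 2 or 3 the count was 228 each, with only both groups in the fit 257, and with every called peak 273.

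The same positions separated the factors in mixtures with ISW2 alone. The index over these regions was 1.53 ± 0.18 with Abf1+ISW2 (n = 6) and -1.20 ± 0.16 with Reb1+ISW2 (n = 3), and all 6 Abf1+ISW2 libraries lay above all 3 Reb1+ISW2 libraries. ISW2 without a factor lay between them at 0.73 ± 0.27 (n = 2), near the 0.78 to 1.01 of the 4 SGD libraries. Either factor without a remodeller stayed near SGD as well, at 0.72 with Abf1 and 0.87 with Reb1 (n = 1 each), and Reb1 with RSC gave 0.78 (n = 1). Abf1+ISW1a reached 1.63 ± 0.21 (n = 10) against 1.14 ± 0.01 with ISW1a (n = 2), whereas Abf1+RSC gave 1.22 ± 0.11 and RSC 1.12 ± 0.07 (n = 3 each). Exact permutation tests over 5 comparisons gave Abf1+ISW2 against Reb1+ISW2 p = 0.0119 (the smallest possible, difference 2.73, adjusted p = 0.0379). Abf1+ISW1a exceeded ISW1a by 0.49 in the mean, and 10 of 10 libraries lay above both ISW1a libraries (exact p = 0.0152, the smallest possible, adjusted p = 0.0379). Abf1+ISW2 against ISW2 (difference 0.80, exact p = 0.0357, the smallest possible) had an adjusted p of 0.0595, ISW2 against Reb1+ISW2 (difference 1.94) an exact adjusted p of 0.125, and Abf1+RSC against RSC (difference 0.10) an exact p of 0.5.

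Over the regions called with only both mixtures in the fit, Abf1+ISW2 exceeded Reb1+ISW2 by 2.56 and Abf1+ISW1a exceeded ISW1a by 0.71 (exact adjusted p = 0.0379 each). The difference between Abf1+ISW2 and Reb1+ISW2 was 2.67 within MNase-Seq, 2.81 within MNase-ChIP-Seq and 2.70 among PSU libraries. The first 2 values had too few libraries to pass (exact adjusted p = 0.125 and 0.312). Without Reb1+ISW2 replicate 1, 2 or 3 it was 2.66, 2.72 and 2.82, each with an exact adjusted p of 0.0595, and without ISW1a replicate 1 or 2 the excess of Abf1+ISW1a was 0.50 and 0.48 with an exact adjusted p of 0.125.

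**Figure D2:**
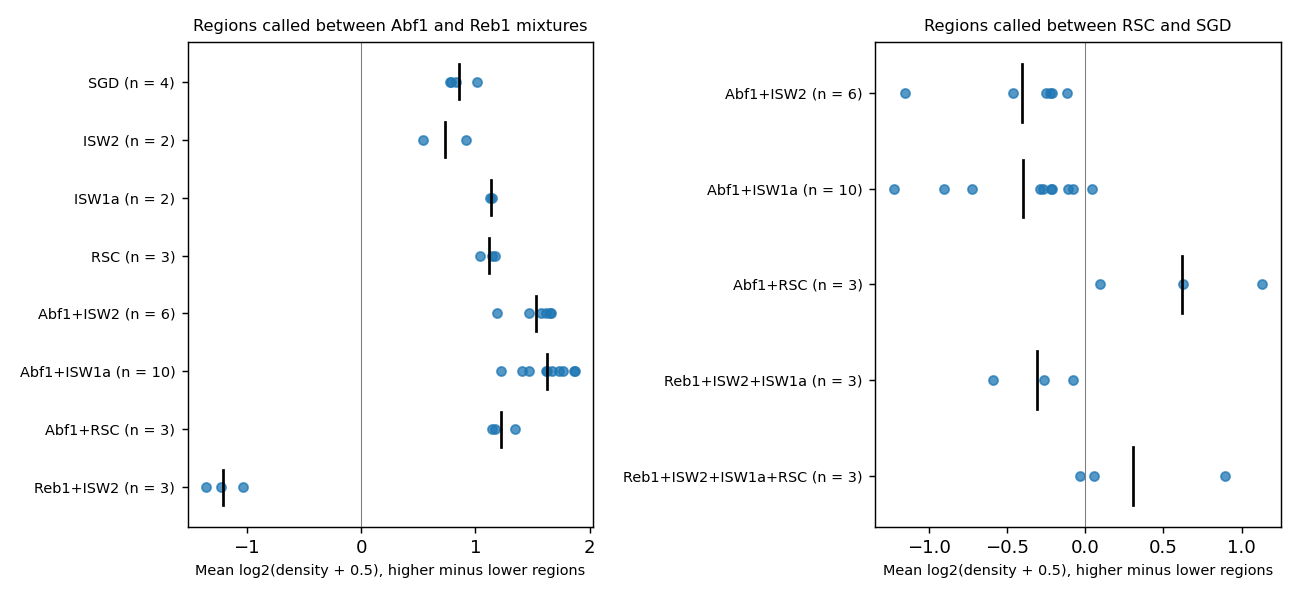
Index per library (horizontal axis, mean log2(density + 0.5) of the regions called higher minus that of the regions called lower) in groups (vertical axis) over the regions called between the Abf1 and Reb1 mixtures (left) and between RSC and SGD (right). Points are libraries and vertical bars are group means. Of the groups shown on the left, only Reb1+ISW2 (n = 3) has libraries below 0, and on the right the Abf1+RSC libraries average 0.62.

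Abf1 was also compared with its absence, with ISW2 or ISW1a as the remodeller. Abf1+ISW2 (n = 6) differed from ISW2 (n = 2) in 119 higher and 119 lower regions. This balance was 174 and 533 without ISW2 replicate 2 and 380 and 629 with peaks at or above the median score. At chromosome 15, 432155, density was 3.99 ± 0.35 with Abf1 and 0.00439 ± 0.00621 without (log2 difference 3.51, limma adjusted p = 0.0162). At chromosome 6, 54255, it was 0.0826 ± 0.136 with Abf1 and 4.82 ± 0.571 without (log2 difference -3.39, adjusted p = 0.000651). Abf1+ISW1a (n = 10) differed from ISW1a (n = 2) in 38 higher and 46 lower regions. This balance was 56 and 247 with peaks at or above the median score and 25 and 9 with every called peak. Among the 38 and 46 regions were neighbouring positions on chromosome 13: density was higher at 30355 (3.0 ± 0.323 against 0.0235 ± 0.0135, limma adjusted p = 0.00169) and lower at 30255 (0.237 ± 0.0752 against 4.82 ± 0.752, adjusted p = 0.00383). Of the lower regions, 18.5% with ISW2 and 6.52% with ISW1a had a higher region within 200 bp. These shares were 0.840% and 2.17% when the lower regions were shifted by 1 kb. The ISW2 count of 238 was 92 without ISW2 replicate 1, 707 without ISW2 replicate 2, 1905 within MNase-ChIP-Seq and 377 with the sample code prefix in the model. The ISW1a count of 84 was 14 and 201 without ISW1a replicates 1 and 2.

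Mixtures of ISW1a and ISW2 tested which of these enzymes sets the spacing when both are present. With Abf1, the repeat length was 186 ± 5.49 bp with ISW2 (n = 6), 178 ± 2.78 bp with ISW1a (n = 10) and 178.5 ± 2.59 bp with both (n = 6). With Reb1 it was 182 ± 1.53 bp with ISW2, 176 ± 1.15 bp with ISW2 and ISW1a, and 176 ± 1.15 bp when RSC was also added (n = 3 each). In the extract it was 189.7 ± 4.73 bp with ISW2 (n = 3), 177 ± 1.41 bp with ISW1a (n = 2) and 178 ± 1.13 bp with both (n = 7). With Abf1 and in the extract, mixtures with both enzymes thus lay nearer to the ISW1a value than to the ISW2 value at the first maximum. In both the group means turned when spacing was taken from the second maximum, through a few libraries with long values, as given below. Abf1+ISW2 exceeded Abf1+ISW1a by 7.97 bp (permutation p = 0.00125, adjusted p = 0.0125 over 10 comparisons), with 4 of 6 libraries above all 10 of the others. The repeat was shorter with ISW1a added to Abf1+ISW2 (difference -7.67 bp, exact permutation p = 0.013, adjusted p = 0.0433), as in the extract (difference -12.1 bp, exact p = 0.00833, the smallest possible, adjusted p = 0.0417). With Reb1 the difference was -6.0 bp (exact p = 0.1, the smallest possible). Mean strand offsets were also shorter with both enzymes than with ISW2. They were 149.8 against 156.5 bp with Abf1, 128.9 against 143.7 bp in the extract and 143.3 against 152 bp with Reb1. Whether fragment length contributed to the shorter repeat was not tested. Abf1+ISW2+ISW1a differed from Abf1+ISW1a by 0.30 bp (permutation p = 0.851). Differences in repeat length when a factor was added to a remodeller did not pass the test: Abf1 with ISW2 differed by 1.67 bp, Abf1 with ISW1a by -4.3 bp, Abf1 with RSC by -2.0 bp and Reb1 with ISW2 by -2.83 bp (exact adjusted p from 0.273 to 0.938). Without replicates 1 and 2 of the remodeller alone, these were 0.167 and 3.17 bp for Abf1 with ISW2, 0.2 and -8.8 bp for Abf1 with ISW1a and -4.33 and -1.33 bp for Reb1 with ISW2. Abf1 with RSC ran from -3.0 to -1.0 bp when single libraries were left out.

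The difference between Abf1+ISW2 and Abf1+ISW1a was 4.22 bp within MNase-Seq, 13.7 bp within MNase-ChIP-Seq and 8.0 bp among PSU libraries (exact p = 0.0682, 0.25 and 0.00333), so that neither assay alone kept the call. The effect of ISW1a with Abf1 was -4.17 bp within MNase-Seq (exact p = 0.0952), -8.4 bp among PSU libraries (exact p = 0.0238) and -4.0 bp between the LMU libraries (n = 1 each). The difference in the extract was -8.43 bp within MNase-Seq, which held 1 library with ISW2, -14.5 bp among PSU libraries (1 against 2) and -8.33 bp among LMU libraries (6 against 1). Without extract+ISW2 replicate 1, 2 or 3 it was -12.9, -9.43 and -13.9 bp, each with an exact adjusted p of 0.0926. From the second maximum, the differences in the Abf1 mixture and in the extract were -7.92 and -15.2 bp and no longer passed, and Abf1+ISW2+ISW1a exceeded Abf1+ISW1a by 15.8 bp (permutation p = 0.00637, adjusted p = 0.0318). Mean spacing from the second maximum in the extract was 196 bp with both enzymes (n = 7), 176 bp with ISW1a (n = 2) and 211.5 bp with ISW2 (n = 3). The mean of the mixture thus lay nearer to ISW2 there too. Its libraries fell apart, however, into 221, 223.5 and 222.5 bp in replicates 3, 4 and 5 and 175 to 178.5 bp in the others. With Abf1 and both enzymes, replicate 2 stood at 235.5 bp and the others at 167.5 to 185.5 bp. Abf1+ISW2 replicate 1 stood at 229 bp. These means therefore rest on a few libraries. In 6 of the 88 libraries the second maximum fell at a limit of its search, among them extract+ISW2 replicate 3, without which the ISW2 value was 197.5 bp and the difference -1.21 bp. With peaks of a single strand, the 3 calls ended, at 7.23, -8.0 and -12.1 bp.

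The extract comparisons asked how array contrast changed when enzymes were returned to an extract that lacks ISW1, ISW2 and Chd1, mostly with 1 library each. Array contrast, the height of the first maximum of the pair correlation over the trough after it, was 1.99 with wild-type extract and 0.571 with the extract lacking these enzymes (n = 1 each), against 1.71 ± 0.153 in SGD (n = 4). Strand offsets, which follow the length of the digested fragments, were 149 and 136 bp in these extract libraries. SGD, without remodeller or extract, scored above the extract with Chd1, ISW1b or RSC alone. Contrast is therefore not by itself a measure of arrays made by enzymes. Returning ISW1a to the extract gave 2.62 ± 0.618 (n = 2), from 2.18 in MNase-Seq at an offset of 144 bp and 3.05 in MNase-ChIP-Seq at 156 bp. ISW1a gave 3.0 with Chd1 at an offset of 168 bp, 1.97 with ISW1b and 1.79 with RSC (n = 1 each), and 1.52 ± 0.292 with INO80 (n = 2). Chd1 alone gave 1.35 at an offset of 151 bp, ISW1b 1.03 at 139 bp and RSC 0.885 at 160 bp (n = 1 each). ISW2 gave 1.78 ± 0.959 (n = 3), from 2.04 and 2.59 in MNase-ChIP-Seq at offsets of 152 and 151 bp and 0.725 in MNase-Seq at 128 bp. The extract without additions was MNase-Seq, so its nearest match was the library at 0.725. The libraries with ISW1a and no ISW2 had longer offsets than the extract without additions, and their higher contrast was not separated from the length of the fragments. Those with ISW1a and Chd1 or ISW1a and ISW1b were MNase-ChIP-Seq, so they also differed from it in assay. A long offset did not always go with high contrast, as in the library with RSC alone. With ISW2 and ISW1a the contrast ran from 0.479 to 1.82 over 7 libraries and was lowest where the strand offset was shortest. Without extract, contrast in mixtures with RSC varied. It was 1.02 ± 0.288 with RSC alone (n = 3), 0.627 ± 0.123 with Abf1 (n = 3) and 0.353 with Reb1 (n = 1), but 1.22 ± 0.451 in Reb1+ISW2+ISW1a+RSC (n = 3) and 1.82 ± 0.0364 in Abf1+ISW2+ISW1a+ISW1b+RSC+Chd1 (n = 2). The extract with ISW2 and ISW1a differed from the extract with ISW2 in 464 higher and 121 lower regions by limma. The balance turned within MNase-Seq (108 higher, 282 lower) and with only these groups in the fit (467 higher, 1450 lower). At chromosome 16, 925805, density was 3.37 ± 1.24 with both (n = 7) and 0.173 ± 0.0475 with ISW2 (n = 3; log2 difference 2.93, adjusted p = 3.09e-05). At chromosome 6, 57455, it was 0.0688 ± 0.0838 and 3.70 ± 0.789 (log2 difference -3.04, adjusted p = 0.0136). These regions could not be separated from the sample code prefix or the assay. Of the 7 libraries with both enzymes 6 were LMU, and of the 3 with ISW2 the 2 PSU libraries were the only MNase-ChIP-Seq ones. With the prefix as a term and the assay in the model, the count went from 585 to 423 in the fit of all groups and from 1917 to 2274 in the fit of both groups. Without the assay, the latter went from 557 to 90. In the fit of all groups the count was 217 without extract+ISW2 replicate 2, 1869 without replicate 3, 115 with every called peak and 1788 without the assay in the model.

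INO80 gave the longest repeat length of the 88 complete lists. It was 206 bp, with a jackknife SE over chromosomes of 1.88 bp, above the 170 to 173 bp of the SGD libraries. INO80Arp8Δ gave 180 bp with the same SE. INO80 shared 27.4% of its positions with SGD and INO80Arp8Δ 42.1%, and their median distances were 218 and 202 bp. In mixtures with other remodellers the repeat was shorter, 181 bp with ISW2, RSC and ISW1a and 179 bp when ISW1b and Chd1 were added as well. In the extract INO80 gave 193 ± 8.49 bp (n = 2) and INO80 with ISW1a 179 ± 2.83 bp (n = 2), and in rsc3-ts extract INO80 gave 183 bp. INO80, INO80Arp8Δ, both pure mixtures and the rsc3-ts extract had 1 library each and no replicate check.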

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

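The tests of fragment length, of splits of the libraries, of thinning to fewer peaks and of the prefix within the extract groups alone were chosen after the results were seen, while thinning to an equal number of peaks and the prefix as a term in the fit of all groups were not.

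Abf1+ISW2 replicate 6 stood apart from its group in the share of positions it had in common with SGD. The share was 43.3%, against 17.2 to 26.8% in the other 5 libraries, and the gap to the nearest of them was 0.632 of the whole range. It was the only one of 20 group values tested this way to stand out, and chance alone gives about 1 in 20. The index, which was not tested this way, was also lowest in this library. Over the ISW2 regions it was -0.07, against 0.96 to 1.36 in the other 5. Over the RSC regions it was -1.15, against -0.46 to -0.11. The library stayed in every comparison of its group. The test looks at 1 library at a time. Abf1+ISW1a replicates 3, 9 and 10 shared 45.0, 47.6 and 40.9% with SGD, against 23.9 to 31.8% in the others of that group, and were not flagged.

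INO80 had a repeat length 26 bp above INO80Arp8Δ, in libraries whose strand offsets differed by 2 bp, which argues against digested fragment length as the whole cause. The number of peaks, 96634 against 95373, does not account for it either: thinned to an equal number, 100 draws of the INO80 list gave 205 to 207 bp. That removed few peaks, but thinned to 47686 peaks they gave 191 to 219 bp, against 180 bp for INO80Arp8Δ. In the extract, the INO80 libraries gave 199 bp at an offset of 168 bp and 187 bp at 144 bp, the direction that fragment length would give, so part of the spread may come from digestion. A remodeller difference, with wider spacing by INO80 that depends on Arp8, is a candidate explanation and stays a hypothesis, since each had 1 library and the spread between repeats of either is unknown.

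The extract with ISW2 and ISW1a differed from the extract with ISW2 in 557 regions when these groups alone were fitted without the assay, and 5 of 100 splits of the 10 libraries gave as many in such fits, the real one included, so chance was not excluded. The highest other split gave 3777 regions and parted exactly the LMU from the PSU libraries, which points to a structure of the samples that follows the sample code. In the fit of all groups the count was 423 with the prefix as a term and 585 without it, and a count that high had been set beforehand to count against the prefix, but that bound was wrong, since 71.0% of the information on the prefix in that fit comes from other groups. In fits of these groups alone the prefix took the count from 557 to 90 without the assay and from 1917 to 2274 with it, where the comparison rests on the 1 MNase-Seq library with ISW2. The enzyme, the prefix and the assay therefore cannot be told apart for these regions, because only 1 library with both enzymes was PSU and both PSU libraries with ISW2 were MNase-ChIP-Seq.

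In the other comparisons with at least 3 libraries in each group, fitted in the same way, only the real split reached its count of regions. No share below 1 of 35 or 1 of 84 was possible there, so the splits cannot exclude chance. Comparisons with a group of 2 were not split. For RSC against SGD, 1 of 35 splits, the real one, gave as many as 9762 regions, and limma called 0 regions in every other split (4691 to 26135 positions at an unadjusted p under 0.05, against 43138 in the real one). For the Abf1 and Reb1 mixtures, 1 of 84 splits, the real one, gave as many as 257 regions, while the highest other split came close at 230. By positions at an unadjusted p under 0.05, 22 of the 84 splits reached the 10738 of the real one, with up to 18606, so that measure did not set it apart.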

How the results depend on the processing

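All alternatives for repeat length, density regions and the region index, and those of single strands, the stricter filter for sharing and pairs of the same sample code prefix, were chosen after the data were seen; the others were fixed before the data were examined. Of 527 values recomputed, 402 kept their direction and their side of the threshold or stayed within 1.5 times the count. Another 62 counts moved further, 37 values lost and 1 gained a call, and 25 changed sign. Sharing within against between treatments kept its sign and call under all 6 alternatives, and the median spacing kept its sign except for Chd1. The causes of the changes were not tested, except that single assays and left-out libraries have fewer samples and often cannot reach the threshold. Reads per library are unknown, and the density model recovered between 0 and 24.5% of simulated changes of 2 in log2, so smaller changes were mostly not detectable. The planned results at start codons, promoters, poly(dA) runs and motifs, with their alternatives, were not run.

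With MNase-Seq libraries only, the spacing difference of Chd1 from SGD became 7.5 bp and the ISW1a difference in gaps became 87.2 per Mb. Repeat length lost its calls at 4.22 bp for Abf1+ISW2 against Abf1+ISW1a, at -4.17 bp for ISW1a added to Abf1+ISW2 and at -8.43 bp in the extract. The index lost its calls at 1.46 for Abf1+RSC against Abf1+ISW2, at 2.67 for Abf1+ISW2 against Reb1+ISW2 and, over the ISW2 regions, at 0.62 for Abf1+ISW2 against Abf1+ISW1a. The Chd1 count went from 708 to 275. With MNase-ChIP-Seq libraries only, calls were lost at 13.7 bp for Abf1+ISW2 against Abf1+ISW1a and, for the index, at 0.32 and 1.00 for Abf1+RSC against Abf1+ISW2 and Abf1+ISW1a, at 2.81 for Abf1+ISW2 against Reb1+ISW2 and at 1.80 over the ISW2 regions. Counts were 210 for SWI/SNF (133 as reported), 1366 for Chd1, 4343 for ISW2 (2891) and 1905 for Abf1+ISW2 against ISW2 (238).

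From the second maximum of the pair correlation, the difference from SGD turned to -5.33 bp for RSC, -0.50 bp for SWI/SNF, -15.5 bp for Chd1, -16.5 bp for ISW1a and -15.0 bp for ISW1b. Abf1 added to ISW1a turned to 2.65 bp. Reb1 added to ISW2 gave 14.1 bp, but in Reb1+ISW2 replicate 1 the second maximum fell at the limit of its search, and without it the difference was -3.75 bp and kept its sign. ISW1a added to Abf1+ISW2 lost its call at -7.92 bp and the extract at -15.2 bp (-1.21 bp without extract+ISW2 replicate 3, which also lay at that limit). Abf1+ISW2+ISW1a against Abf1+ISW1a gained a call at 15.85 bp. The mean behind that call included 235.5 bp in Abf1+ISW2+ISW1a replicate 2, against 167.5 to 185.5 bp in the others of that group. With single strands, calls were lost at 7.23 bp for Abf1+ISW2 against Abf1+ISW1a, -8.0 bp for ISW1a added to Abf1+ISW2 and -12.1 bp in the extract, and signs turned to -0.667 bp for Abf1 added to ISW2 and -0.767 bp for Abf1+ISW2+ISW1a against Abf1+ISW1a. These 2 were -0.167 and -0.933 bp with every called peak. With peaks weighted by score, Chd1 turned to -0.25 bp, and ISW1a added to Abf1+ISW2 lost its call at -8.17 bp. With peaks at or above the median score, that call was lost at -7.83 bp, gaps turned to 18.0 per Mb for SWI/SNF and 14.7 per Mb for ISW1a, and the index of Abf1+RSC against RSC turned to -0.06.

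With every called peak, counts fell to 71 for SWI/SNF, 406 for Chd1, 142 for ISW1b, 273 for the Abf1 and Reb1 mixtures, 156 for Abf1+ISW2 against ISW2, 34 for Abf1+ISW1a against ISW1a and 115 for the extract. With peaks at or above the median score they were 833, 1856, 1262, 827, 1009, 303 and 1054 in the same order, and 912 for ISW1a. Without the assay term they were 1794 for ISW1a, 456 for ISW1b and 1788 for the extract. With only the compared groups in the fit, limma called 0 for SWI/SNF, Chd1 and ISW2 (12210, 20165 and 31648 positions at an unadjusted p under 0.05), 4843 for ISW1a, 2984 for ISW1b, 257 for the Abf1 and Reb1 mixtures, 107 for Abf1+ISW2 against ISW2, 316 for Abf1+ISW1a against ISW1a and 1917 for the extract. For ISW1a and ISW1b that fit in effect used the 1 MNase-Seq library of SGD. The prefix as a term gave 377 for Abf1+ISW2 against ISW2. The 2 pseudocounts tried moved no count by over 1.5 times. Which direction had more regions turned under 6 of 13 alternatives with regions for SWI/SNF, 6 of 14 for Chd1, 4 of 14 for ISW1a, 2 of 14 for ISW1b, 1 of 15 for RSC and 0 of 13 for ISW2. It turned under 2 of 11 for the Abf1 and Reb1 mixtures, 2 of 10 for Abf1 added to ISW1a and 2 of 11 for the extract. Abf1+ISW2 against ISW2 was even, so it had no larger direction to turn. Over regions called with only the compared groups in the fit, all 8 index differences for RSC and for the Abf1 and Reb1 mixtures kept their sign and their side of the threshold, and ISW2 had no such regions.

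Single libraries were left out only from the smaller groups. None was left out of Abf1+ISW2, Abf1+ISW1a, Abf1+ISW2+ISW1a or the extract with both enzymes, so ranges that involve these groups may be too narrow. The ranges were as follows. Spacing of Chd1 ran from -13.6 to 6.88 bp and turned without Chd1 replicate 2. Gaps ran from -22.9 to 123 per Mb for RSC, -41.1 to 36.3 for SWI/SNF and -87.3 to 20.3 for ISW1a, and turned without RSC replicate 3 for RSC, without SWI/SNF replicate 1 or SGD replicate 1 or 3 for SWI/SNF, and without ISW1a replicate 1 or SGD replicate 3 for ISW1a. Repeat length ran from 0 to 8.0 bp for Chd1 and 6.0 to 15 bp for ISW1a against SGD, from -8.8 to 0.2 bp for Abf1 added to ISW1a, turning without ISW1a replicate 1, and from -13.9 to -9.43 bp in the extract. It ran from 0.167 to 3.17 bp for Abf1 added to ISW2, where only ISW2 libraries were left out. Abf1+ISW2 replicate 1, at 196 bp the highest of its group, always stayed in, so the sign is not secured. The repeat length ran from -3.0 to -1.0 bp for Abf1 added to RSC, -4.33 to -1.33 bp for Reb1 added to ISW2 and -0.667 to 0.667 bp for RSC added to Reb1+ISW2+ISW1a. The index ran from 0.76 to 1.28 for Abf1+RSC against Abf1+ISW2 and from 0.76 to 1.28 against Abf1+ISW1a, from 2.66 to 2.82 for Abf1+ISW2 against Reb1+ISW2 and from 0.48 to 0.50 for Abf1+ISW1a against ISW1a. Counts ran from 4940 to 9309 for RSC, 82 to 155 for SWI/SNF, 222 to 824 for Chd1, 8 to 537 for ISW1a, 160 to 371 for ISW1b, 243 to 2701 for ISW2, 228 to 302 for the Abf1 and Reb1 mixtures, 92 to 707 for Abf1+ISW2 against ISW2, 14 to 201 for Abf1+ISW1a against ISW1a and 217 to 1869 for the extract. A group left with 1 library was assumed to vary like the others.

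The labels give no shared batch for a replicate number, and the data did not show that the numbers pair the libraries. In the 11 compared pairs of groups that share 2 or more numbers, deviations of libraries with the same number correlated between -0.101 and 0.157. The highest values, 0.157 and 0.0764, came from the 2 numbers shared by Abf1+ISW2 and Reb1+ISW2. Where 5 numbers were shared, most libraries did not correlate best with their own number. With the replicate number as a block, limma called 0 regions for RSC against SGD (23625 positions at an unadjusted p under 0.05) and 0 for the Abf1 and Reb1 mixtures (6230 positions), in fits of only the libraries with shared numbers. The blocked repeat length differed by 7.0 bp for Abf1+ISW2 against Abf1+ISW1a (exact sign-flip p = 0.0625) and by -5.4 bp for ISW1a added to Abf1+ISW2 (exact p = 0.25). The blocked index was 1.04 for Abf1+RSC against Abf1+ISW2, 1.31 against Abf1+ISW1a and 2.79 for Abf1+ISW2 against Reb1+ISW2, each with an exact sign-flip p of 0.5, the smallest that 2 shared numbers allow. It was 0.74 for Abf1+ISW2 against Abf1+ISW1a over the ISW2 regions (5 shared numbers, exact sign-flip p = 0.125). These calls could not pass under the block, as even 5 shared numbers allow no sign-flip p below 0.0625, and the block changed no other call.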

Other observations

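The tests of array contrast and of ISW1a between contexts, which are all the tests in this part, were chosen after the results were seen.

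A few stretches held a large part of the summed peak score. The median shares of the 4 bins of 5 kb with the highest medians added up to 25.7%, among them chromosome 5, 115001 to 120000, with a median of 9.93% (5.17 to 16.6% over 88 libraries), and chromosome 4, 450001 to 455000, with 6.52% (3.38 to 10.9%). Scores were not compared between libraries, so these shares entered no test.

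The shorter repeat with ISW1a added to ISW2 was compared between contexts, in each of which the mean strand offset was shorter as well. The difference was -12.1 bp in the extract, -7.67 bp with Abf1 and -6.0 bp with Reb1. Permutation of the libraries between contexts gave adjusted p-values of 0.397 for the extract against Abf1, 0.397 for the extract against Reb1 and 0.744 for Abf1 against Reb1, so no difference between contexts was detectable.

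Array contrast differed widely among the 7 extract libraries with ISW2 and ISW1a, from 0.479 to 1.82. It rose with the strand offset, which ran from 109 to 142 bp (Pearson r = 0.914, exact permutation p = 0.00417, adjusted p = 0.00833 over 2 relations; Spearman rho = 0.964, exact permutation p = 0.00278). Without the 2 libraries farthest from the median offset r was 0.933, and among the 6 LMU libraries it was 0.918 (exact permutation p = 0.00972). The degree of digestion may therefore account for low contrast in part of these libraries, although a library with poorer arrays may also be cut further, and the labels do not say whether digestion was varied. The number of nucleosomes stays open as an explanation: r was -0.171 (exact permutation p = 0.715; Spearman rho = 0.0, exact permutation p = 1.0) and 0.722 without the 2 farthest libraries, and 7 libraries are too few to decide.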
